A study of Homo sapiens with 3 samples.

How the data were processed

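Total RNA of LS174T-tetON-NICD cells was labelled by an amino allyl aRNA procedure and hybridised to two-colour oligonucleotide arrays, per the labels. Each array carried 27456 spots, of which 24460 were gene probes and 2680 were blanks. Per the labels, the untreated control was in Cy5 and the treated sample in Cy3 on each of the 3 arrays, which held TNF (50 ng/ml), doxycycline (100 ng/ml) and both for 24 h. Each condition had 1 culture and 1 array.

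The scanner values are the median intensity of each spot at both wavelengths on a linear scale, and per the file headers they combine scans at several gains. The series table holds values that the authors deposited as log2 ratios. They were recomputed here as log2 of Cy3 over Cy5, each channel less the trimmed mean of the blanks, minus the median of the array. All 18330, 19535 and 19605 deposited log2 values of the TNF, doxycycline and combined arrays were matched within 0.001, which settled the direction as treated over control. The table was empty for 6130, 4925 and 4855 probes.

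The deposited local background intensity followed the spot signal (r on the log scale over probes of 0.931, 0.960 and 0.942 in Cy5 and 0.922, 0.948 and 0.917 in Cy3), so it was not used in the main setting. The 5%-trimmed mean of the blanks of each channel was the background instead. Signals were corrected with normexp (saddle-point fit, offset 50) and normalised within each array by loess with limma 3.58.1 in R 4.3.3, with control spots given no weight. A channel was above background when it exceeded the 95th percentile of the blanks. Probes above background in at least 1 channel of every array were kept, and 3 probes marked as bad on the TNF array were dropped.

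Of the 24460 probes, 20236 had 1 gene symbol and 4224 had none. Symbols were brought up to date with a current gene table, which left 17238 as they were and updated 2899, while 99 without a match were kept. Probes of 1 gene were averaged, and 16336 probes gave 14529 genes, 1747 of them with several probes. Ratios with a channel not above background or with a saturated spot are given as limits. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome coordinates of the probes were used.

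Comparisons were each treatment over control, the combined array minus each single one, and the combined log2 ratio minus the sum of the single ones. Genes at least 2-fold higher or lower were counted. No test was possible with 1 array per condition, and the number of arrays limits the precision. No paired analysis was possible because each group held 1 replicate. For a gene list, the median was placed among the medians of 10000 random lists of the same size matched on signal in 20 bins. The 28 lists were fixed before the data were examined, as were the comparisons and most of the other settings tried. Percentiles below 2.5 or above 97.5 are described as low or high.

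Named genes followed a rule fixed before the data were examined. For each single treatment these were the 12 highest and 12 lowest genes by the value nearer to 0 of both readings. For both treatments together they were the 10 highest and 10 lowest by the value nearest to 0 against control and each single treatment, and the 5 furthest above and 5 furthest below the sum with at least a 2-fold ratio on the combined array. NOTCH1, HES1, OLFM4, UBD, ATOH1, MUC2, TNFAIP3, CXCL8 and LGR5 were always named, and up to 4 members were named per list. Further genes were chosen after their values were seen, namely LCN2, the members listed in other comparisons for contrast, and those of the closing section.

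The procedure was tested on simulated arrays of 19041 probes. For control signals above 500, the median recovered share of the true log2 change was 92.4%, 94.8% and 95.7% on the TNF, doxycycline and combined arrays; for dimmer probes it was 50.1%, 63.8% and 69.0%. Of 4-fold changes in dim probes, 41 of 81, 50 of 71 and 55 of 71 passed 2-fold, and 0 unchanged probes did. The simulated noise was set small, so that the 0 follows from the setting. Real probes of 1 gene differed with an SD of 1.01, 0.267 and 0.289 on the TNF, doxycycline and combined arrays. The simulation therefore gives no rate of false 2-fold calls for the real arrays, least of all for the TNF array. Of 500 simulated lists of 20 genes with no shift, 6.4%, 5.0% and 4.8% lay outside the central range. With a shift of 0.3, 87.6%, 100.0% and 98.4% lay above it. These lists were drawn at random from the same genes, so the shares with no shift follow from the construction. They do not cover lists whose members vary together. The simulated lists were matched on the control signal of the doxycycline and combined arrays. The real lists were matched on the mean signal of both channels over all arrays, so the shares do not check that matching.

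Other settings fixed before the data were examined were no background subtraction, normexp with offset 16, median centring, Aquantile normalisation between arrays, the authors' processed values, no filter on dim probes, a filter on both channels, the brightest probe per gene, and thresholds of 1.5-fold and 3-fold. Turned dye signs were to be tried only if arrays correlated below -0.3; the lowest correlation over all probes was 0.191, so this was not run. Settings added after the data were seen were the local background with normexp, a dim filter that ignored the TNF array, and single effects of opposite sign set to 0 before the sum.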

Results

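Gene expression was profiled in LS174T-tetON-NICD, a line derived from the human colon carcinoma line LS174T in which doxycycline switches on the Notch intracellular domain (NICD), the active fragment of the Notch receptor. Cells were treated for 24 h with tumour necrosis factor alpha (TNF, 50 ng/ml), with doxycycline (100 ng/ml) or with both, and each treated culture was hybridised against an untreated control on 1 two-colour oligonucleotide array. The treated RNA carried Cy3 and the control RNA carried Cy5 on all 3 arrays. The design thus gave 1 culture and 1 array per condition, no dye swap and no doxycycline-treated cells without NICD, so effects of NICD and of doxycycline itself are not separated. No p-value can be given for any difference below, and all counts and list percentiles describe these arrays only.

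The arrays held 24460 probes, and 14529 genes entered the comparisons. Control probes above background numbered 19427 on the TNF array, 19203 on the doxycycline array and 19272 on the array of both treatments (the combined array). Treated probes above background numbered 17869, 20156 and 20465 in the same order. The median treated signal was 70.0 on the TNF array, against 121 on the doxycycline array and 126 on the combined array. The control channels of the 3 arrays gave a technical yardstick, since all hold untreated cells. The labels do not say whether they are aliquots of 1 RNA. Between 2 arrays their log2 levels differed with an SD of 0.102 (TNF and doxycycline arrays), 0.119 (TNF and combined arrays) and 0.0753 (doxycycline and combined arrays), and 4, 5 and 1 of the 14529 genes differed by 2-fold or more.

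The treated channel of the TNF array stood apart. Among 8005 probes with a bright control signal, 851 were at least 4-fold lower on the TNF array, against 6 on the doxycycline array and 29 on the combined array. Different probes of 1 gene disagreed there by an SD of 1.01 on the log2 scale (573 genes, 1151 probes), against 0.267 on the doxycycline array and 0.289 on the combined array. Each single treatment was therefore read in 2 ways that share no array. TNF was read as TNF over control and as the combined array minus the doxycycline array, and doxycycline as doxycycline over control and as the combined array minus the TNF array. Over all 14529 genes the 2 readings correlated at r = -0.05 for TNF and 0.10 for doxycycline, so as a whole they did not agree. The 12 highest and 12 lowest genes named for each single treatment were chosen to have the same direction in both readings. Their shared direction therefore follows from this choice.

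**Figure D1:**
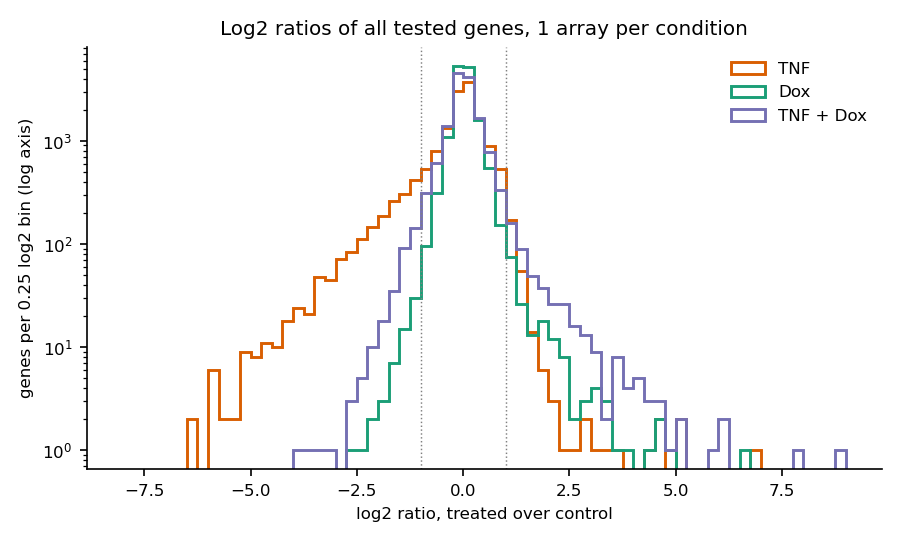
Histogram of the log2 ratio of treated over control for the 14529 genes on each of the 3 arrays, in bins of 0.25 log2 units on a log count axis; dotted lines mark 2-fold changes. The TNF array has a long tail of low ratios, with 1790 genes at least 2-fold lower, against 59 on the doxycycline array and 310 on the combined array.

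The first comparison asked what TNF did to these cells. Genes that NF-kB, the transcription factor activated by TNF receptors, is known to control were higher with TNF. The chemokine genes CCL20 and CXCL2 reached log2 ratios of 6.99 (127-fold) and 5.08 (33.8-fold) over control, and CXCL8, the gene of interleukin-8, reached 5.22 (37.3-fold). BIRC3, which encodes an inhibitor of apoptosis, stood at 4.69 (25.8-fold). Feedback inhibitors of the pathway were also higher, with TNFAIP3 at 3.48 and NFKBIA at 2.95.

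In the second reading, TNF on top of doxycycline, the same genes stood at 3.93 or more (CCL20), 2.37 (CXCL2), 4.00 (BIRC3), 2.85 (TNFAIP3) and 2.47 (NFKBIA). CXCL8 stood at 0.93 there. The highest gene by the value nearer to 0 of both readings was UBD, which encodes the ubiquitin-like modifier FAT10, at 4.28 and 7.38. The second value is approximate, since the treated spot was saturated on the combined array and the control signal lay near background. LTB, the gene of lymphotoxin beta, followed at 4.61 and 4.26, then CXCL1 (3.52 and 2.25), RELB (2.13 and 2.54), CXCL3 (3.20 and 1.98), OPTN (1.89 and 1.99) and PSMB9 (1.80 and 1.61), a subunit of the immunoproteasome. The control signal of LTB was 132 on the TNF array against 7.11 and 30.6 on the others, so that its ratio on the TNF array could be understated.

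Of 41 measured genes on the list of NF-kB and TNF targets, 19 were at least 2-fold higher and 2 at least 2-fold lower with TNF, and the list median of 0.82 lay at percentile 100 of 10000 random lists of similar signal. With TNF on top of doxycycline, 15 were higher and 0 lower, with a median of 0.64 at percentile 100. The medians were 0.41 and 0.61 with no filter on dim probes, and 1.43 and 1.12 in the authors' processed values. Interferon-stimulated genes formed the other list that stood high in both readings, with 4 of 43 higher and 2 lower over control (median 0.35, percentile 100), and 7 higher and 0 lower over doxycycline (median 0.40, percentile 100). IFI6 reached 2.36 with TNF alone and OAS3 2.04, while IFI35 stood at or below -2.17 and BST2 at -1.51. IFIT3 and ISG20 reached 1.76 and 1.49 over doxycycline.

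Lower ratios with TNF in both readings were found for CLDN2, the gene of the pore-forming tight junction protein claudin-2 (-4.12 and -1.37), SLC7A5, a subunit of an amino acid transporter (-2.98 and -1.10), SLC6A20 (-3.43 and -1.21), GPRC5A (-3.24 and -1.07) and ETV4, an ETS transcription factor (-2.08 and -1.37). The probe annotated to the metallothionein gene MT4 stood at -2.50 and -2.23. Genes of cell division in this group were UHRF1 (-2.29 and -1.35), HJURP (-1.27 and -1.26) and TPX2 (-1.30 and -1.25). The remaining members were MFSD2A (at or below -2.64, and -1.30), MLXIPL (-1.19 and -1.14) and MALL (-1.35 and -1.09). The 2 probes of UHRF1 differed with an SD of 2.35 on the TNF array, and those of MALL with an SD of 1.86.

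Tight junction and epithelial adhesion genes had a low median on the TNF array, -0.73 at percentile 0.57, with 11 of 22 lower and 3 higher. CLDN4 stood at -4.84 and CLDN7 at -4.77. With TNF on top of doxycycline the same list had a median of 0.06 at percentile 87.2, with 1 gene lower and 2 higher. Low medians on the TNF array alone were also seen for Notch pathway target genes (-0.28, percentile 1.82, 5 of 21 lower and 0 higher; CD44 -2.11, CCND1 -2.03) and for Notch receptors, ligands and modifiers (-0.24, percentile 1.25, 4 of 27 lower and 0 higher; PSENEN -1.41). Over doxycycline these stood at 0.05 (percentile 84.8) and 0.03 (percentile 78.8).

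In all, 262 genes were at least 2-fold higher and 1790 at least 2-fold lower with TNF over control, and 172 were higher and 132 lower with TNF on top of doxycycline. Higher in both readings were 27 genes, where independent lists would share 3.10, and lower in both were 22, where independent lists would share 16.3. In the main setting the lower group was therefore close to what unrelated lists of these sizes would give. It held 41 genes with offset 16, 32 with the local background and 82 in the authors' processed values, where the number for unrelated lists was not computed. With median centring in place of loess the TNF array gave 761 higher and 1804 lower, and the authors' processed values gave 1854 and 3066.

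**Figure D2:**
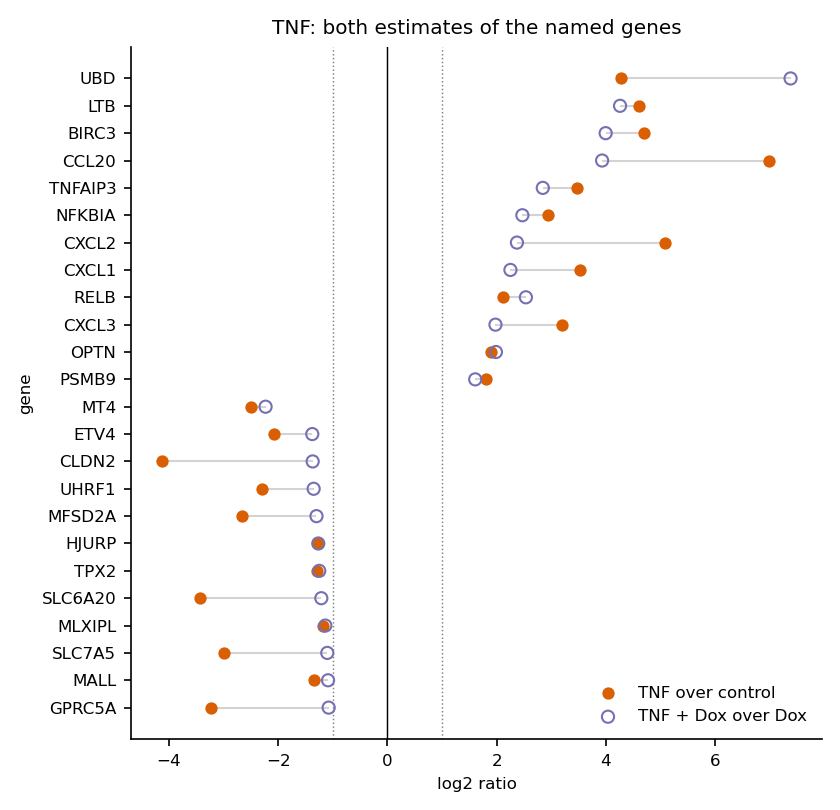
Log2 ratios of the 24 genes named for TNF in both readings, 1 array per condition: filled points show TNF over control and open points show the combined array minus the doxycycline array; dotted lines mark 2-fold changes. Values of the 12 higher genes lie between 1.61 and 7.38, and the 12 lower genes lie at or below -1.07; the open point of UBD is approximate because of saturation and a dim control.

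The second comparison asked what NICD induction by doxycycline did. The transgene itself was not resolved: the 2 probes of NOTCH1 averaged -0.43 with doxycycline, but the part of the gene they match and the species and extent of the NICD construct are not given in the sources used here, so this value checks nothing. Known Notch targets were higher. HES5 stood at 3.13 (8.77-fold), HEYL at 2.69, HES4 at 2.41 and HES1 at 1.35 (2.56-fold), all transcriptional repressors of the HES and HEY families. OLFM4, an intestinal stem cell marker and Notch target, was the highest of all at 6.73 (106-fold).

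Relative to TNF alone, the same genes stood at 3.92 (HES5), 3.10 (HES4), 2.84 (HEYL), 0.78 (HES1) and at least 8.48 (OLFM4, saturated on the combined array). Of 21 measured Notch pathway targets, 6 were at least 2-fold higher with doxycycline and 0 lower, with a median of 0.26 at percentile 100 (0.57 with median centring, 0.44 with a smaller offset of 16 and 0.49 in the authors' processed values). On the combined array 7 were higher and 0 lower, with a median of 0.58 at percentile 100. On top of TNF, 9 were higher and 0 lower (median 0.69, percentile 100.0). The list stood low on the TNF array itself (median -0.28, 5 lower and 0 higher), which raises this reading. Of all genes 14.0% were higher in it.

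Many of the other high genes are not classical Notch targets. PLA2G2A, a secreted phospholipase of Paneth cells, stood at 4.54 over control and 5.21 over TNF. TFF1, a trefoil peptide of mucous cells, stood at 4.94 and at least 4.54. SERPINA12 (4.51 and 5.81), KRT13, a keratin of stratified epithelia (4.31 and 4.47), and IGFL1 (3.95 and 5.68) followed. SLC2A1, the glucose transporter GLUT1, stood at 3.55 and 4.03, BEST4, a chloride channel of a subset of colonocytes, at 3.45 and 3.62, and IGFBP3 at 3.38 and 4.04. The remaining members were TDO2, a tryptophan dioxygenase (3.03 and 3.78), and CAPN10 (3.04 and 4.34). The control signals of SERPINA12, IGFL1 and BEST4 rose with the treated signal between arrays (for SERPINA12 13.3, 28.6 and 108 on the TNF, doxycycline and combined arrays), so that these ratios could be understated.

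Lower with doxycycline in both readings were NUPR1, a stress-induced nuclear protein (-2.70 and -2.75), PROC, the gene of protein C (-1.93 and -3.12), DOK7 (-2.01 and -1.79), FAIM2 (-2.16 and -1.67) and MT4 (-1.72 and -1.45). MUC2, the main secreted mucin of goblet cells, stood at -1.55 over control and -2.76 over TNF. Over control it stood at 1.28 with TNF and -1.48 with both, so part of the -2.76 is the higher TNF value. RGS2 (-1.25 and -1.99), PLD6 (-1.24 and -2.10), NUAK2 (-1.25 and -1.86), FUT3 (-1.24 and -1.69), CRYBB1 (-1.31 and -1.42) and ENTPD8 (-1.32 and -1.27) completed the group. With the local background of the scanner, an alternative chosen after seeing the data, FUT3 turned to 0.076 over control and FAIM2 to 0.87 over TNF. MUC2 turned to 0.0054 on the combined array, where its treated signal was 9.60 over the blank spots. ATOH1, the transcription factor that specifies secretory cells, stood at -0.05 with doxycycline, with signals close to background (6.09 in the control and 9.19 in the treated channel over the blank spots).

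Goblet and secretory genes had a slightly low median of -0.07 at percentile 1.70, with 2 of 31 higher (TFF1 4.94, KLK10 1.86) and 2 lower (MUC2 -1.55, SPINK4 -1.16). Over TNF the median was 0.02 at percentile 40.5, with 5 higher and 3 lower. Absorptive enterocyte genes included 4 of 28 higher and 0 lower, namely GUCA2A, the gene of guanylin (2.21), CEACAM6 (1.36), DPP4 (1.08) and FABP1 (1.07), and their median of 0.09 lay at percentile 96.6, inside the range of most random lists. Over TNF 9 were higher and 1 lower (median 0.39, percentile 99.6). Stem cell and Wnt target genes had a median of -0.11 at percentile 0.87, with 3 of 22 lower (SMOC2 -1.65, ZNRF3 -1.40, LGR5 -1.03) and 0 higher. Over TNF this low median was not repeated (-0.01, percentile 23.4, 3 higher and 3 lower). Genes of the integrated stress response under ATF4 had a median of -0.22 at percentile 0.02, with 3 of 24 lower (NUPR1 -2.70, SLC7A5 -1.94, SLC3A2 -1.01) and 0 higher. Over TNF it was -0.31 at percentile 0.67, with 6 lower and 4 higher. With median centring, the medians of the stem cell and stress response lists turned to 0.04 and 0.14 while the median of all genes moved from 0.01 to 0.14.

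Small upward medians were also seen on the doxycycline array for NF-kB and TNF targets (0.17, percentile 99.9, 2 of 41 higher and 0 lower; CXCL2 1.82, PTGS2 1.27) and for interferon-stimulated genes (0.14, percentile 100.0, 0 of 43 higher and 0 lower; ISG15 0.78). Over TNF neither was repeated as a high median: the NF-kB list stood at -0.12 (percentile 1.73) and the interferon list at 0.16 (percentile 93.2).

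In all, 171 genes were at least 2-fold higher and 59 at least 2-fold lower with doxycycline over control. With doxycycline on top of TNF, 2036 were higher and 478 lower, and this reading holds the low values of the TNF array. Higher in both readings were 122 genes, where independent lists would share 24.0, and lower in both were 23, where independent lists would share 1.94. With median centring the doxycycline array gave 540 higher and 19 lower, and 219 and 8 in both readings, so that the number of lower genes depends on the centring; the authors' processed values gave 452 higher and 182 lower.

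**Figure D3:**
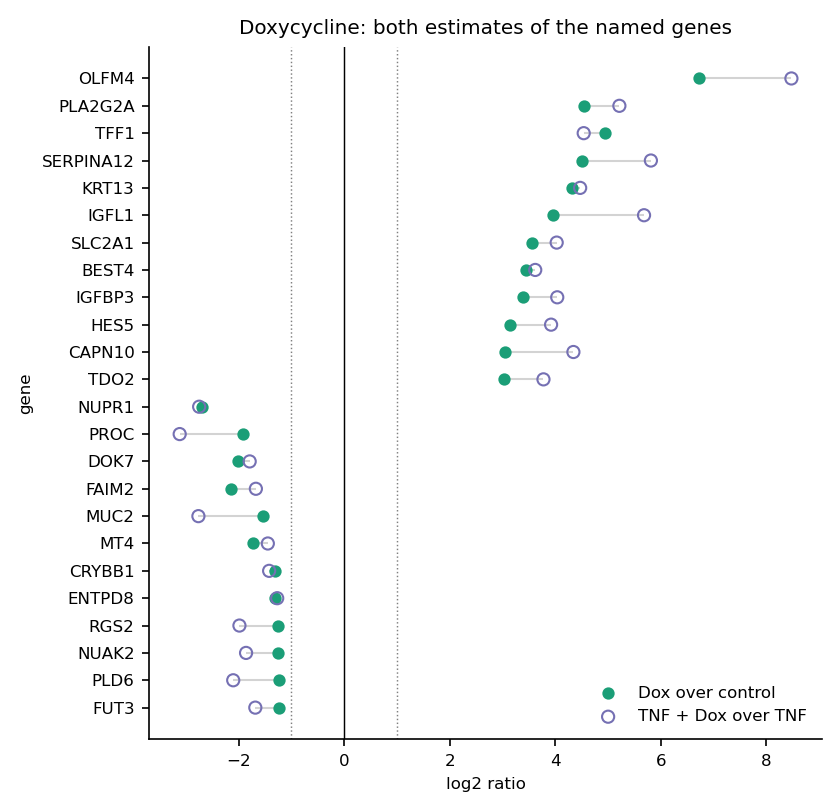
Log2 ratios of the 24 genes named for doxycycline in both readings, 1 array per condition: filled points show doxycycline over control and open points show the combined array minus the TNF array; dotted lines mark 2-fold changes. The 12 higher genes lie at or above 3.03 and the 12 lower genes at or below -1.24; the open points of OLFM4 and TFF1 are lower limits because of saturation.

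The third comparison asked what both treatments did together. Some genes were far higher with both treatments than with either alone. UBD reached at least 8.81 (449-fold), against 4.28 with TNF and at least 1.39 with doxycycline. PI3, the gene of the protease inhibitor elafin, stood at 3.95 (15.5-fold), against 0.13 with doxycycline and a control too dim to read on the TNF array. CTSS, the lysosomal protease cathepsin S, stood at 4.77 (27.3-fold), against 1.30 and 1.46. TNFSF10, the death ligand TRAIL, stood at 3.84 (14.3-fold), against 0.94 and 1.11.

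GUCA2A, the guanylin gene, reached 5.23 (37.4-fold), against 0.04 with TNF and 2.21 with doxycycline. IGFL1 reached 6.11, against 0.43 and 3.95, and the amino acid transporter gene SLC6A14 reached 3.53, against 0.45 with doxycycline. The fructose transporter gene SLC2A5 reached 3.33, against 0.92 with doxycycline, with TNF alone at or below -0.31. ACKR3, an atypical chemokine receptor, reached 3.11, against 0.06 and 0.18, and SDCBP2 reached 2.68, against -1.46 and 0.53. The control signal of GUCA2A was 13.5, 13.8 and 137 on the TNF, doxycycline and combined arrays, and that of PI3 rose alike, so that their ratios could be understated.

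Genes lowest with both treatments, and less low with either, were DUSP6, a phosphatase that limits ERK signalling (-2.28, against -0.57 with TNF and -0.59 with doxycycline), E2F2, a transcription factor of the cell cycle (-1.95, against 0.31 and -0.35), VGF (-2.16, against -0.31 and -0.64), TNS4 (-2.22, against -0.75 and -0.63) and ID2 (-1.48, against 0.29 and -0.05). With the local background of the scanner ID2 turned to 0.87 on the combined array. The mitotic kinesin gene KIFC1 stood at -1.46 (0.09 and 0.05 with the single treatments) and the centromere protein gene CENPA at -1.43 (0.12 and -0.04). MT4 (-3.95, against -2.50 with TNF and -1.72 with doxycycline), ZDHHC8BP (-2.57, against -1.03 and -1.10) and CRYBA4 (-2.56, against -0.41 and -1.13) were already at least 2-fold lower with 1 or both single treatments. The 2 probes of TNS4 differed with an SD of 1.63 on the combined array.

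**Figure D4:**
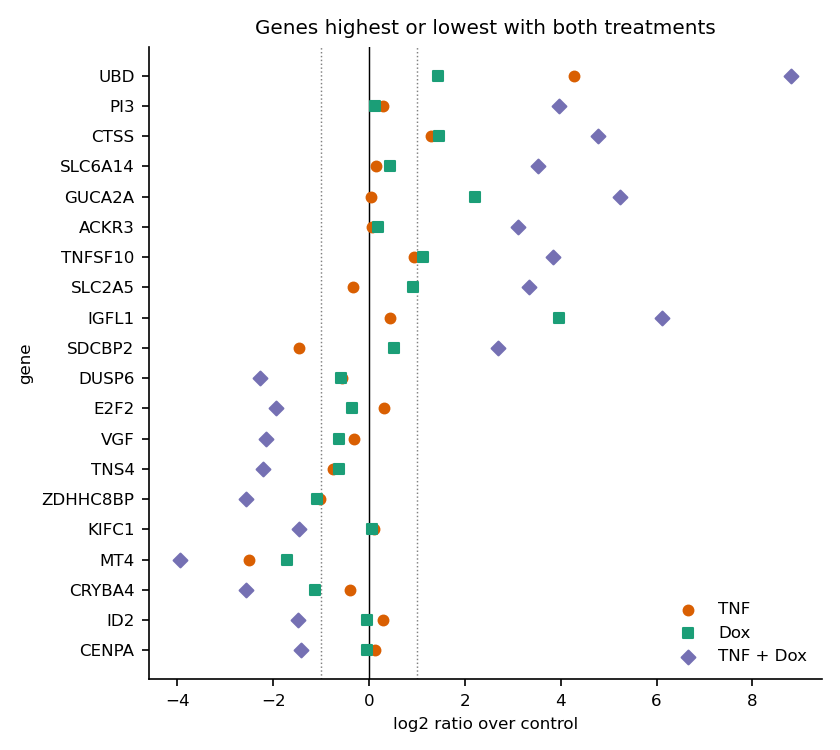
Log2 ratios over control on the 3 arrays for the 10 genes highest and the 10 genes lowest with both treatments relative to control and to each single treatment, 1 array per condition; dotted lines mark 2-fold changes. UBD lies furthest right at 8.81, a lower limit because of saturation, and MT4 furthest left at -3.95.

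Proliferation genes stood lower with both treatments: 20 of 38 were at least 2-fold lower and 0 higher over control, with a median of -1.02 at percentile 0. CDC6 and MCM2, which license DNA replication, stood at -1.80 and -1.80, and AURKB, a mitotic kinase, at -1.51. On top of doxycycline 16 were lower and 0 higher (median -0.93, percentile 0; GINS2 -1.49, FOXM1 -1.38). With doxycycline alone 0 were lower and 0 higher (median -0.07, percentile 6.58). With TNF alone 11 were lower and 0 higher, and the median of -0.16 lay at percentile 30.9.

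Genes of MHC class I antigen presentation stood higher with both treatments, with 7 of 17 at least 2-fold higher and 0 lower (median 0.67, percentile 100): after UBD these included PSMB9 at 2.13, B2M, the light chain of MHC class I, at 1.68, and TAP1, a subunit of the peptide transporter, at 1.30. With TNF alone 2 were higher and 5 lower (median -0.28, percentile 15.3), and the low members included HLA-E (at or below -3.22) and PSMB8 (-2.33), read on the array whose bright probes were often low. With TNF on top of doxycycline 7 were higher and 0 lower (median 0.80, percentile 100). Interferon-stimulated genes included 12 of 43 higher and 0 lower on the combined array (median 0.58, percentile 100; IFIT3 2.15, ISG20 1.88). NF-kB and TNF targets included 18 of 41 higher and 0 lower (median 0.67, percentile 100).

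Apoptosis and death receptor genes had a median of 0.54 at percentile 100 with both treatments, with 5 of 20 higher and 0 lower (TNFSF10 3.84, BID 1.72, CASP4 1.34, CASP1 1.19). With the local background BID turned to -0.090. The p53 target list had a median of 0.24 at percentile 98.2, with 3 of 20 higher, namely BTG2, an antiproliferative factor (2.40), CDKN1A, the cell cycle inhibitor p21 (2.05), and PHLDA3 (1.27), and 1 lower (GDF15 -1.46). On top of doxycycline the p53 list had a median of 0.34 at percentile 100 (BTG2 2.08, CDKN1A 1.34), and the apoptosis list one of 0.39 at percentile 100.0. In the apoptosis list 2 of 20 were higher and 0 lower there. BID stood at 1.48 on top of doxycycline, but at -1.06 with the local background.

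Stem cell and Wnt target genes were lower, with 8 of 22 at least 2-fold lower and 0 higher (median -0.44, percentile 0.01): SMOC2 stood at -1.99, LGR5 at -1.89 and ZNRF3 at -1.66. On top of doxycycline the median was -0.29 at percentile 0.01, with 1 of 22 lower (EPHB2 -1.29). Integrated stress response genes included 4 of 24 lower and 0 higher (median -0.49, percentile 0; NUPR1 -3.47, SLC7A5 -3.04, TRIB3 -1.48). Hypoxia and glycolysis genes had a median of -0.23 at percentile 1.82, with SLC2A1 higher at 4.30 and CA9 and HK2 lower at -1.12 and -1.04; the median turned to 0.21 with median centring, where the median of all genes was 0.13, and to 0.10 with the local background. Oxidative phosphorylation genes had a median of 0.22 at percentile 99.5, with 0 of 31 at least 2-fold higher and 0 lower; on top of doxycycline it was 0.09 (percentile 98.2), and -0.02 in the authors' processed values.

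Cytosolic ribosomal proteins (0.11, percentile 99.9) and endoplasmic reticulum stress genes (0.21, percentile 99.8) stood slightly high on top of doxycycline, with 0 genes of either list at least 2-fold higher and 0 lower, and the ribosomal median turned to -0.01 in the authors' processed values. Other lists stayed within the central 95% of random lists on the combined array. Their medians over control were -0.09 for goblet and secretory genes, 0.11 for absorptive enterocyte genes, 0.04 for Notch receptors and ligands, -0.01 for MHC class II, -0.06 for enteroendocrine genes, 0.06 for Paneth cell genes, 0.12 for tight junction and adhesion genes, -0.13 for cholesterol synthesis, -0.07 for metallothioneins, -0.09 for immediate early genes, -0.13 for mitochondrial ribosomal proteins, -0.01 for matrix and mesenchymal genes and -0.11 for housekeeping genes. Markers of blood cells (percentile 46.2) and of fibroblasts and endothelial cells (percentile 30.0), which this line should lack, did likewise. On the TNF and doxycycline arrays the lists not described above also stayed in that range, with medians from -0.55 (cholesterol synthesis) to 0.15 (housekeeping genes) with TNF and from -0.13 (endoplasmic reticulum stress) to 0.24 (metallothioneins) with doxycycline. For doxycycline over TNF, which holds the low values of the TNF array, medians outside that range were 1.23 for apoptosis (percentile 100.0), 1.12 for MHC class I (percentile 100.0), 0.92 for p53 targets (percentile 99.6), 0.85 for tight junction genes (percentile 99.5), 0.31 for cytosolic ribosomal proteins (percentile 97.9; -0.65 in the authors' processed values), -0.39 for housekeeping genes (percentile 1.18) and -0.67 for proliferation genes (percentile 0). For TNF over doxycycline the stress response list stood at -0.19 (percentile 2.20).

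**Figure D5:**
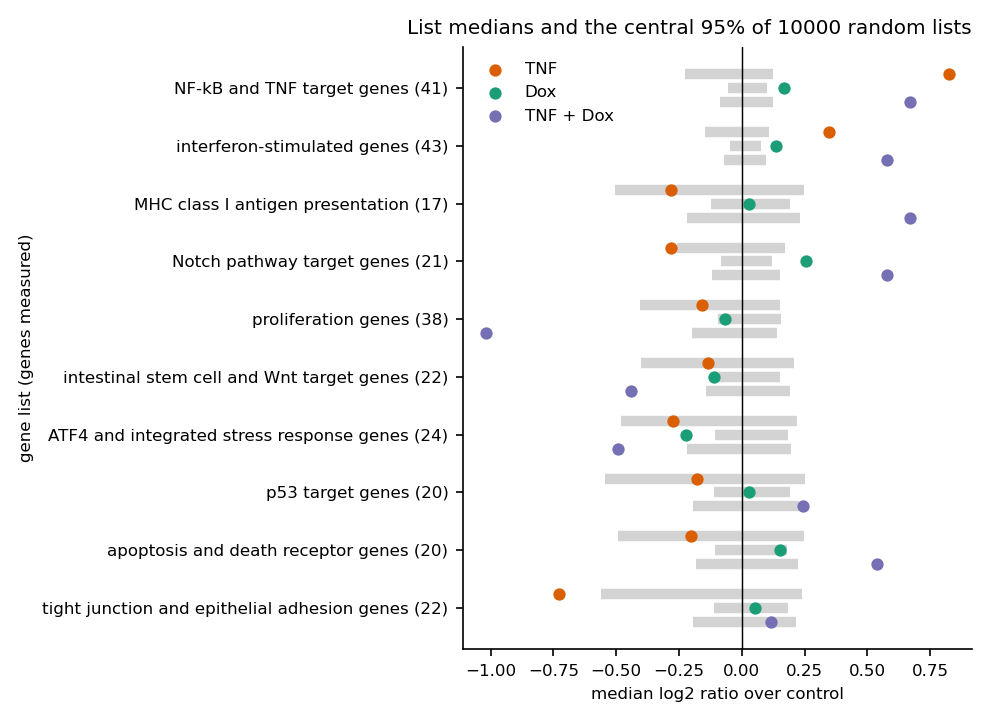
Median log2 ratio over control of 10 gene lists on the 3 arrays (points; number of measured genes in brackets), with grey bars for the central 95% of medians of 10000 random lists of similar signal. Proliferation genes lie at -1.02 on the combined array, against -0.16 and -0.07 on the TNF and doxycycline arrays. With median centring the doxycycline medians of the stem cell and stress response lists turn to 0.04 and 0.14. The median of all genes moves from 0.01 to 0.14 there.

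In all, 460 genes were at least 2-fold higher and 310 at least 2-fold lower with both treatments over control. Median centring gave 965 higher and 135 lower, and the authors' processed values 993 and 756. Of the 171 genes higher with doxycycline, 148 were also higher with both treatments, where independent lists would share 5.41 and simulated unchanged samples with 1 shared control shared 2. Of the 59 lower genes 53 were also lower, against 1.26 and 1. Of the 262 genes higher with TNF, 59 were also higher with both, against 8.30 and 2, and of the 1790 lower genes 121 were, against 38.2 and 1. Over genes, which are not independent replicates, the log2 ratios of the doxycycline and combined arrays correlated at r = 0.755 (covariance 0.135). Those of the TNF and combined arrays correlated at r = 0.206 (covariance 0.0904). The simulated shared control gave r = 0.505, set by its construction, and a covariance of 0.00524. The TNF and doxycycline arrays, which share no treatment, correlated at r = 0.372 (covariance 0.105). They shared 25 higher genes, against 3.08 for independent lists, and 33 lower genes, against 7.27. The overlap of the TNF and combined arrays is therefore not read as a repeated TNF effect. Part of each overlap can come from a control shared by the arrays and from any dye bias of single probes. Neither could be measured, since there was no dye swap and the labels do not say whether the controls are 1 RNA. The simulation drew its noise from the spread of the control channels between arrays. It lacks any deviation or dye bias common to the arrays and the noise of the treated TNF channel, so it gives no baseline for these overlaps.

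The last comparison asked whether both treatments together gave more or less than the sum of the single log2 ratios. Among genes at least 2-fold higher or lower on the combined array, those furthest above the sum were DPEP1 (5.85), LGALS3 (5.75), TUBA1C (5.43), MCM7 (5.41) and CTNNB1 (5.29). All 5 had very low ratios on the TNF array, at -6.34, -5.45, -5.51, -5.74 and -4.10, and each rests on 1 probe. On the combined array they stood at -2.32, 1.58, -1.32, -1.02 and 1.36, close to the doxycycline array for DPEP1 (-1.83), LGALS3 (1.29), TUBA1C (-1.24) and MCM7 (-0.69).

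Among the same genes, those furthest below the sum were IQGAP3 (-3.07), CCL20 (-3.06), EREG, the gene of the growth factor epiregulin (-2.77), CXCL2 (-2.71) and STEAP1 (-2.19), which rest on 1 probe each; the value of CCL20 is approximate, since its treated signal with doxycycline lay near background. EREG stood at 1.51 with TNF, -0.04 with doxycycline and -1.30 with both, and IQGAP3 at 1.59, 0.45 and -1.03. Within the NF-kB list, CXCL8 stood at 5.22 with TNF and 0.51 with both, a difference of -4.71, CCL20 at 6.99 and 3.79, and LCN2, the gene of lipocalin-2, at 2.87 and 0.33. CXCL8 (-4.29) and LCN2 (-2.23) also lay below the sum, but were less than 2-fold higher on the combined array. Between both treatments and TNF, the NF-kB list had a median of -0.12 at percentile 1.73. The central range of random lists ran from -0.10 to 0.32 in this comparison, which holds the low values of the TNF array. Of the 41 genes 8 were at least 2-fold higher and 5 lower, whereas 14.0% of all genes were higher and 3.29% lower. Members thus moved both ways, while the list median lay slightly below that range. Apart from CXCL8, CCL20 and LCN2, the members at least 2-fold higher with TNF differed by -1.71 to 1.28 between both treatments and TNF. Among them NFKBIA changed little (2.95 with TNF and 2.91 with both), BIRC3 was slightly lower (4.69 and 4.38) and RELB was higher (2.13 and 2.74).

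In all, 2032 genes were at least 2-fold above the sum and 742 at least 2-fold below it. Median centring gave 2145 above and 1442 below, and the authors' processed values 3426 and 2645. Of the 2032, 1617 were at least 2-fold lower on the TNF array, whose low values raise this difference by its definition. When single effects of opposite sign were set to 0, an alternative chosen after seeing the data, 103 genes stayed above and 60 below. For the genes above the sum these were the negative single effects. Among the 103 were GUCA2A (2.98 above the sum) and ACKR3 (2.87), and also PI3, SLC6A14 and UBD, whose sums rest on limits and are not given.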

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

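All tests weighed here were chosen after the results were seen. The bounds of the probe-pair tests on the TNF array were changed after their values were seen, and a first version with 50% bounds had counted against a loss of signal in single probes and for a decrease of the genes' RNA. Differences between effects listed here were not tested, since each rests on 3 arrays.

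Some single effects had opposite directions without and with the other treatment. The TNF effect on CTNNB1, the gene of beta-catenin, was -4.10 without and 1.18 with doxycycline, a difference of 5.29. That on SDCBP2 was -1.46 and 2.15, a difference of 3.61. That on EREG was 1.51 and -1.26, a difference of -2.77, and that on IQGAP3 was 1.59 and -1.48, a difference of -3.07. The doxycycline effect on DPEP1 was -1.83 without and 4.02 with TNF, a difference of 5.85. That on TUBA1C was -1.24 and 4.19, a difference of 5.43, and that on GPRC5A was -1.13 and 1.04, a difference of 2.16. Of list members named for other reasons, HLA-E had TNF effects at or below -3.22 without and of 1.35 with doxycycline (a difference of 4.63 before the limit is applied), and SLC3A2 had doxycycline effects of -1.01 without and 1.84 with TNF, a difference of 2.85. In all, 48 genes had effects of opposite sign and at least 2-fold each way. Of 3037 probes above background but without a gene symbol, 1 was at least 4-fold higher on the doxycycline array, at 2.47, against 39 named genes.

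The low ratios of bright probes on the TNF array, CTNNB1 and DPEP1 among them, were weighed with pairs of probes of 1 gene. Where 1 probe was at least 4-fold lower, the other was at least 2-fold lower in 52.4% (95% Wilson interval 44.3 to 60.5), against 31.9% of all probes of such pairs. This counts against a loss of signal that strikes each probe independently as the whole cause. The pairs were not matched on signal, so a loss that depends on signal, or that the probes of 1 gene share for another reason, is not weighed by it. The 6 of 24 blocks of the array with most low probes held 31.0% of them and 24.6% of all bright probes, which counts against a region of the array. Of 619 genes with a bright control and at least 4-fold lower on the TNF array, 12 (1.94%, 1.11 to 3.36) were at least 2-fold lower with TNF on top of doxycycline and 62 on the combined array, which counts against a decrease of RNA by TNF that also occurs with doxycycline. A decrease only without doxycycline, mixed with lost signal, may stay open. The other probe was less than 2-fold lower in 47.6% of pairs (39.5 to 55.7). No limit for this share was fixed beforehand, and the combined array held 5 such pairs to compare. Over all pairs the log2 ratios of the 2 probes correlated at r = 0.372 on the TNF array. On the doxycycline and combined arrays r was 0.598 and 0.789. This disagreement argues against a decrease that lowers all probes of a gene alike as the whole cause, on this 1 array.

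The 2032 genes above the sum of the single effects were weighed next. Of these, 79.6% were at least 2-fold lower on the TNF array, and 5.07% stayed above the sum with negative single effects set to 0. Both shares follow in part from how the genes were selected, since a low value on the TNF array raises the difference by definition. They therefore decide neither for low values on that array nor against a response to both treatments beyond each single one, and both may stay open.

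CXCL8, LCN2 and CCL20 were lower with both treatments than with TNF, with log2 differences of -4.71, -2.54 and -3.20. The other 16 members of the NF-kB list that were at least 2-fold higher with TNF had a median difference of -0.49 (range -1.71 to 1.28). This lay above the limit of -2 chosen for a like decrease of the whole list, although selecting high TNF values pushes it down. The 3 genes were picked as the most decreased of these members and the limit was set near them, so the rest were bound to lie above these 3. The median shows only that the other 16 did not fall as far, and a smaller decrease of the list is not excluded. All 41 members had a median of -0.12 (percentile 1.73), with 8 higher and 5 lower. Of 11 genes at least 6-fold higher on the TNF array, 9.09% lay outside the list, but these 3 genes are among the 11, so this decides nothing about spuriously high probes. Such probes, and an effect of NICD or of doxycycline on these 3 genes, stay open.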

How the results depend on the processing

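The local background, the dim filter without the TNF array and the opposite-sign setting were tests chosen after the data were seen; the other alternatives were planned. Each choice was changed alone, except that the authors' processed values differ in background, scaling and probe set at once. Except where a threshold itself was changed, the cause was not tested. Of the values of single genes under the alternatives, 1800 stayed within the spread between control channels and 1136 moved by more than that. Another 6 that were at least 2-fold changed direction. These totals mix settings that recompute each ratio with filters and probe choices that seldom alter it. No background subtraction moved 146 values (152 stayed), offset 16 moved 220 (78 stayed) and median centring 247 (51 stayed). The authors' processed values moved 256 (30 stayed) and the local background 247 (45 stayed, 6 changed direction). With Aquantile, the dim filters and the brightest probe, at most 14 moved each. Of counts and list medians answering a comparison, 140 stayed close and 84 moved. Aquantile normalisation cannot move a log2 ratio by its construction here, and the dim filter without the TNF array moved none of these counts or medians. Dim probes limit the sizes: simulated changes in dim probes were recovered by 50.1% on the TNF array.

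With offset 16, 431 genes were higher with TNF, 101 lower with doxycycline, 469 lower with both and 218 lower with both against doxycycline. In both readings of TNF 47 were higher and 41 lower. List medians were 0.92 for NF-kB targets with TNF, 0.81 for them with both against doxycycline, and 0.44 for Notch targets with doxycycline.

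With median centring, 761 were higher with TNF, 540 higher and 19 lower with doxycycline, 965 higher and 135 lower with both, and 1442 below the sum. In both readings of doxycycline 219 were higher and 8 lower. Medians were 0.57 for Notch targets with doxycycline and 0.73 for NF-kB targets with both against doxycycline.

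With the authors' processed values, 1854 were higher and 3066 lower with TNF, 452 and 182 with doxycycline, 993 and 756 with both, 3411 and 2052 with both against TNF, and 467 and 471 with both against doxycycline. Above the sum were 3426 and below it 2645. In both readings 99 were higher and 82 lower with TNF, and 244 and 63 with doxycycline. Medians were 1.43 for NF-kB targets with TNF, 1.12 for them with both against doxycycline, and 0.49 for Notch targets with doxycycline.

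At 1.5-fold, 1302 were higher and 2790 lower with TNF, 597 and 309 with doxycycline, 1245 and 969 with both, 3306 and 1416 with both against TNF, and 559 and 615 with both against doxycycline. Above the sum were 3207 and below it 1887. In both readings 95 were higher and 162 lower with TNF, and 294 and 70 with doxycycline. At 3-fold, 26 were higher and 972 lower with TNF, 66 and 10 with doxycycline, 184 and 60 with both, 1105 and 93 with both against TNF, and 53 and 4 with both against doxycycline. Above the sum were 1126 and below it 102. In both readings 12 were higher and 1 lower with TNF, and 54 and 4 with doxycycline.

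With the local background, 1181 were lower with TNF, 192 lower with both and 8 lower in both readings of doxycycline, and the medians of NF-kB targets were 0.59 with TNF and 0.57 with both against doxycycline. MUC2 turned to 0.0054 and ID2 to 0.87 with both treatments, FUT3 to 0.076 with doxycycline, and FAIM2 to 0.87 with both against TNF. BID turned to -0.090 with both and -1.06 with both against doxycycline, from 1.72 and 1.48.

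With no background subtraction the medians of NF-kB targets were 0.92 with TNF and 0.69 with both against doxycycline. With no filter on dim probes they were 0.41 and 0.61, and that of Notch targets with doxycycline was 0.20. The NF-kB median with TNF was 0.63 with a filter on both channels and also 0.63 with the brightest probe per gene. With single effects of opposite sign set to 0, 103 were above the sum and 60 below it.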

Other observations

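The test of BEST4 cell markers and the genes named here were chosen after their values were seen. Of 45 measured keratin genes, 3 were at least 2-fold higher on the doxycycline array and 0 lower: KRT13, KRT17 (2.85) and KRT19 (1.42). The median of the 45 was 0.04, and KRT7 and KRT80 stood at -0.40 and -0.79. On the combined array 6 were higher, with KRT5 (1.48), KRT6A (1.51) and KRT6B (1.66) added, and 1 was lower. Of 4 measured IGFL genes, 3 were higher on both arrays: IGFL1, IGFL2 (1.64 with doxycycline) and IGFL4 (1.19 with doxycycline). SPARC, a matrix protein gene, stood at 2.83 with doxycycline and 3.75 with both. SNAI2, a transcriptional repressor of epithelial genes, stood at or above 2.70 and 4.21 over a control too dim to read, and LAMA3, a laminin chain gene, at 2.20 and 4.28. The matrix and mesenchymal list as a whole had a median of 0.09 at percentile 96.6 with doxycycline. MT1X, a metallothionein gene, stood at 3.02 with doxycycline.

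BEST4 and GUCA2A were both among the genes higher with doxycycline, and the hypothesis that markers of BEST4-positive colonocytes were gained as a set was tested on a list of 9 other markers written before their values were looked up. The median of the 8 measured was -0.03 on the doxycycline array, at percentile 26.4, which counts against it. NBL1 stood at -0.89 and MEIS1 at 0.47.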
